A study of Homo sapiens with 26 samples.

How the data were processed

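Small RNA was sequenced from SUP-T1 cells, an established human CD4-positive T lymphoblastoid line, after mock treatment or infection with HIV, at 5, 12 and 24 h. Per the labels' protocols, total RNA was ligated to a 3' adaptor designed for microRNA and to a 5' adaptor, amplified by RT-PCR, and size selected on a polyacrylamide gel. The labels describe 26 libraries. The 9 libraries of HIV with UV treatment, and the 6 comparisons planned with them, were not analysed here, because the columns of the tables used here name only mock (M) and HIV (H) libraries. A column name with H and no UV mark was read as HIV infected. This left 17 libraries, with 2 mock libraries at 5 h and 3 libraries in every other group.

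The deposited values are whole-number read counts per small RNA sequence, with 1 table per time point and 1 column per library. BWA is named in the submitters' processing notes, with no version. Its role, the genome build, the microRNA database, the counting tool and any filters are not given in the sources used here. There were 1141 sequences at 5 h, 1435 at 12 h and 110 at 24 h, between 18 and 25 nt long. Column totals ran from 2935841 to 12236917 counts at 5 h and from 3741071 to 7546104 at 12 h. At 24 h they ran from 54219 to 165342. The 24 h table held 3 of the 50 most abundant arms of the 12 h table, so its totals are not library depths and the depth at 24 h is unknown. Counting error is small beside the spread between libraries for the abundant arms, and it limits the arms with few counts. The reads carry no molecular identifiers, so counts are not independent molecules.

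One miRNA arm often stood under different end variants in different libraries, with the count in one row and 0 in the other. Sequences with an identical overlap of at least 16 nt and ends shifted by at most 4 nt were therefore merged into arms, and the highest row was taken in each library. Merging left 937 arms at 5 h, 1146 at 12 h and 88 at 24 h. Names, arms and positions come from an exact match of each sequence to the miRNA precursors of GENCODE v29 on GRCh38, made for this work. Positions were not taken from the authors' files. Where several precursors match, the position of 1 is given. Reads from identical copies cannot be told apart. Sequences with no precursor match are named by their sequence.

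Some counts of 0 may mark an arm that was not listed, rather than one without reads. At 5 h, 228 of 2063 zeros fell where at least 10 counts were expected from the median of the other libraries above 0. The number was 412 of 3286 at 12 h and 33 of 193 at 24 h. The main test was therefore limited to arms above 0 in every library of the table, which passed edgeR's filterByExpr with a minimum count of 10 and a minimum total of 15. This restriction departs from the plan fixed before the data were examined, which named the count filter alone. It left 262 arms at 5 h, 296 at 12 h and 29 at 24 h.

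Each time point was fitted alone with edgeR 4.0.16 in R 4.3.3, by the quasi-likelihood test (glmQLFit and glmQLFTest, robust=TRUE) with TMM scaling. Tests were two-sided with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are HIV infected over mock. Levels are CPM, counts scaled to a common TMM-adjusted column total. The change of the effect between 5 and 12 h was tested as an interaction over the 236 arms that both tables could give. The 24 h table did not enter that test, since it holds a selected part of the libraries. The 19 miRNA lists were fixed before the data were examined. List members were matched by miRNA name without the arm. Either arm of a listed miRNA therefore counted, such as miR-125b-2-3p beside miR-125b-5p. Lists with at least 3 tested arms were tested at 5 and 12 h with camera from limma 3.58.1, at a preset correlation of 0.01 and at an estimated one, and with fry.

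Arms named in the text were chosen by a rule fixed before the data were examined. In each comparison it takes the 10 largest rises and 10 largest falls past the threshold, or all where fewer pass. Where none pass in a direction, it takes the 3 with the smallest unadjusted p in that direction. It also takes members with the smallest unadjusted p from each list. The rule allowed up to 4 per list, and a limit of 2 was set after the data were examined. Other arms named in the closing section were chosen after their values were seen.

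The alternatives chosen before the data were examined were DESeq2 1.42.0, median-of-ratios (RLE) factors, total counts, no count filter, a mean count of at least 50, robust=FALSE, the replicate number as a block, and leaving out each library in turn. Added after seeing the data were the sum of an arm's rows, zeros kept as counts, the deposited sequences unmerged, only arms listed under 1 sequence, and HIV infected library 3 at 5 h thinned to the total of library 2. Matching used Python 3.11.15.

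The fits were tested on simulated data with the means, spread and totals of the real arms. The tables hold too few arms for 200 changed ones, so 48 arms were changed at 5 and 12 h and 6 at 24 h, in 10 simulations each. Over the 262 arms at 5 h, 40.6% of 1.5-fold changes, 85.6% of 2-fold changes and 98.1% of 3-fold changes were recovered. Over the 296 arms at 12 h, the shares were 29.4%, 65% and 93.1%. Over the 29 arms at 24 h they were 10%, 20% and 60%. For the interaction over 236 arms, 52.1% of 2-fold and 86.2% of 3-fold differences were recovered. False calls made up 4% of calls at 5 h, 6.5% at 12 h, 10% at 24 h and 2.4% for the interaction. In these simulations the changed arms were split evenly between rises and falls. The shares therefore do not cover changes in 1 direction only, as called at 24 h. With camera at the preset correlation, a raised list was found in 100% of simulations at both times, and an unchanged list in 6% at 5 h and 2% at 12 h. The arms were simulated independently of each other. These shares therefore do not give the false calls for lists whose arms vary together.

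No libraries were duplicates. The chi-square per degree of freedom between libraries of a group was at least 115.3 at 5 h, 67.9 at 12 h and 3.62 at 24 h. No label says that the libraries of a group came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical.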

Results

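Small RNA was profiled in SUP-T1 cells, an established human T lymphoblastoid line, to follow miRNA levels over the first day of HIV infection. The 5 h table held 2 mock and 3 HIV infected libraries, and the 12 and 24 h tables each held 3 mock and 3 HIV infected libraries. At 5 h the mock libraries had 6013573 and 4976621 counts, and the HIV infected libraries had 3433474, 2935841 and 12236917. At 12 h the mock libraries had 6039217, 3741071 and 4725322 counts, and the HIV infected libraries had 5634294, 5271690 and 7546104. The most abundant arm at both times was miR-181a-5p, a miRNA that tunes T cell receptor signalling. It stood at 333930 ± 18525 CPM in mock libraries (SD, n = 2) and 299870 ± 40978 in HIV infected libraries (SD, n = 3) at 5 h. At 12 h it stood at 289660 ± 21250 and 359080 ± 80100 CPM (SD, n = 3 each), and the difference passed the test at neither time (adjusted p = 0.703 at 5 h and 0.628 at 12 h, edgeR).

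At 5 h, 1 of 262 arms passed the test between HIV infected and mock cells. The arm shared by miR-548aj and miR-548ar, members of a large primate-specific miRNA family derived from a transposon, fell by 0.97 on the log2 scale (SE 0.26, adjusted p = 0.047, edgeR quasi-likelihood test). The call was lost without either mock library and without HIV infected library 1 or 2. The arm went from 13.9 ± 1.03 CPM in mock libraries (SD, n = 2) to 6.77 ± 1.38 in HIV infected libraries (SD, n = 3), and was lower in 3 of 3 infected libraries than in either mock library. The sequence, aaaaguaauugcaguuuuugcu, matches the MIR548AJ2 precursor on chromosome X at 38023947 to 38023968 (GRCh38, minus strand), outside any same-strand host gene, and the reads cannot be assigned to a single copy of the family. No arm passed with a higher level in infected cells. The 3 with the smallest p among higher estimates were miR-500a-3p, miR-5000-3p and miR-2467-5p. For miR-500a-3p, encoded in an intron of CLCN5 on chromosome X (50008482 to 50008504), the estimate was 0.60 (SE 0.18, adjusted p = 0.065), with 650.58 ± 96.1 CPM in mock and 987.19 ± 113.37 in infected libraries. For miR-2467-5p, in an intron of HDAC4 on chromosome 2 (239351772 to 239351793), it was 0.52 (SE 0.17, adjusted p = 0.101). For miR-5000-3p, on chromosome 2 (75090873 to 75090893), it was 0.70 (SE 0.23, adjusted p = 0.101), or 0.38 without mock library 1. With 1 library left out, miR-500a-3p passed at 0.67 without HIV infected library 1 and at 0.49 without HIV infected library 3, miR-5000-3p at 1.05 without mock library 2 and miR-2467-5p at 0.53 without HIV infected library 3.

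Among the fixed lists at 5 h, the miR-30 family had 4 of 5 tested arms with lower estimates in infected cells. With all 5 libraries none passed over all arms, and 2 passed when adjusted over the list alone. These were miR-30d-5p, at -0.46 (SE 0.14), and miR-30c-5p, at -0.36 (SE 0.15). Adjusted over the list alone, 4 passed without HIV infected library 3, 1 without mock library 2 or HIV infected library 1, and 0 without mock library 1 or HIV infected library 2. Of the let-7 family, which represses growth-promoting genes, 7 of 7 arms had higher estimates, such as miR-98-5p at 0.31 (SE 0.14) and let-7i-5p at 0.22 (SE 0.14, or 0.12 without mock library 1), and with RLE factors let-7g-5p turned lower. Without HIV infected library 3 only 4 of 7 let-7 arms were higher, and without HIV infected library 1 6 of 7 were. The miR-17~92 and paralog clusters, which promote lymphocyte proliferation, had 8 of 10 arms with higher estimates and 9 of 10 with total counts, with miR-18a-5p at 0.37 (SE 0.17) and miR-92b-3p at -0.27 (SE 0.15). Of 12 lymphocyte miRNAs, 9 had lower estimates, including miR-150-5p, abundant in mature lymphocytes, at -0.50 (SE 0.19), while miR-146b-5p stood at 0.38 (SE 0.18), or 0.71 without mock library 1 and 0.12 without mock library 2. When HIV infected library 3 was left out, miR-150-5p passed over all arms at -0.64, miR-30d-5p at -0.61, miR-30c-5p at -0.50 and miR-29c-3p at -0.48. The miR-15/16 family had 5 of 6 arms with higher estimates, or 4 of 6 without mock library 2 or HIV infected library 2 or 3, with miR-195-5p at 0.84 (SE 0.33), or 0.54 without HIV infected library 3. Higher estimates were also found for 3 of 3 arms of the miR-183 cluster, with miR-96-5p at 0.41 (SE 0.19), or for 2 of 3, with miR-96-5p at 0.17 (SE 0.20), without HIV infected library 3. The miR-232724 clusters had 4 of 4 arms with higher estimates, or 3 of 4 with RLE factors, without mock library 1 or without HIV infected library 2. The miR-29 family had 2 of 3 arms with lower estimates, or 3 of 3 without mock library 2. miR-221 and miR-222 had 1 each way, but 2 of 2 were higher without mock library 2 and 0 of 2 without HIV infected library 1.

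The lists tied to HIV were divided at 5 h. Of 9 arms of miRNAs reported to bind HIV RNA, 5 had higher and 4 lower estimates. The numbers were 4 and 5 with RLE factors and without HIV infected library 2 or 3. The smallest p was that of miR-150-5p, which is on this list too. Of 10 arms of miRNAs reported to act on host factors of HIV, 7 had higher and 3 lower estimates, or 8 and 2 with total counts. Of 9 interferon or NF-kB responsive arms, 6 had higher and 3 lower estimates, or 4 and 5 without HIV infected library 3, with miR-125a-5p at -0.37 (SE 0.18), which passed over all arms at -0.54 without that library. Of 5 p53-responsive arms, 4 had higher estimates, or 5 with total counts and 3 without HIV infected library 3 or mock library 2, with miR-34a-5p at 0.19 (SE 0.26), or 0.079 without mock library 1, 0.068 without HIV infected library 2 and 0.29 without mock library 2 or HIV infected library 3. Among miRNAs of other cell types, 3 of 4 epithelial arms had higher estimates, with miR-200a-3p at 0.62 (SE 0.33), or 1.24 without mock library 1 and 0.26 without mock library 2, and 3 of 5 mesenchymal or endothelial arms had lower ones, or 2 of 5 with total counts or without HIV infected library 1, 1 of 5 without mock library 1 and 4 of 5 without HIV infected library 2. The liver, muscle or neuron list had 1 tested arm, miR-9-5p, at 0.08 (SE 0.15), or 0.022 without mock library 1, 0.024 without HIV infected library 2 and 0.13 without mock library 2. The myeloid or erythroid, 14q32 and C19MC lists had no tested arm. None of 14 lists passed camera, with 2 at an unadjusted p under 0.05 and a smallest adjusted p of 0.199, and none passed fry. For the miR-30 family the unadjusted p was 0.0173 with camera and 0.290 with an estimated correlation, and for the miR-17~92 and paralog clusters it was 0.0408 and 0.298. Without HIV infected library 3 the miR-30 family passed camera (adjusted p = 0.0145), but not with an estimated correlation (adjusted p = 0.915).

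The 5 h count depended on single libraries, the tool, the scaling and the filter. In the edgeR test of all 5 libraries, 36 arms had an unadjusted p under 0.05. With robust=FALSE another arm, ugucccuguucaggcgcca, was called in place of miR-548aj/miR-548ar-5p. The count was 0 with DESeq2, RLE factors, total counts, a mean count of at least 50, summed rows or unmerged sequences. Without HIV infected library 3 it was 29, of which 8 were higher and 21 lower, without HIV infected library 1 it was 5, without HIV infected library 2 it was 0 and without mock library 2 it was 3. The call of the miR-548aj/miR-548ar-5p arm was lost when either mock library or HIV infected library 1 or 2 was left out, with its estimate between -0.87 and -1.25 over the fits that left out a library.

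At 12 h none of 296 arms passed the edgeR test, with a smallest adjusted p of 0.261. At an unadjusted p under 0.05, 7 arms had higher and 17 lower estimates, and DESeq2 called 1 arm, miR-501-3p. This arm, from the same CLCN5 intron cluster as miR-500a (chromosome X, 50009772 to 50009793), stood at 275 ± 29.9 CPM in mock and 117 ± 39.5 in infected libraries (SD, n = 3 each). Its estimate was -1.23 (SE 0.25), with an adjusted p of 0.261 with edgeR and from 0.00054 to 0.637 over the alternatives. Its counts stood under 2 end variants. Without HIV infected library 3 it was the 1 arm that passed with edgeR, at -1.43. Next came miR-1271-5p, in an intron of ARL10 on chromosome 5 (176367960 to 176367980), at -1.49 (SE 0.37, adjusted p = 0.345). Its level was 6.70 ± 1.79 CPM in mock and 2.31 ± 1.06 in infected libraries, also under 2 end variants. The third, miR-125a-5p, which restrains inflammatory signalling and lies in an intron of SPACA6 on chromosome 19 (51693268 to 51693291), was at -0.61 (SE 0.16, adjusted p = 0.345), lower in 3 of 3 infected libraries. The higher estimates of smallest p were those of miR-3180, from a sequence that matches either arm, at 1.07 (SE 0.29, adjusted p = 0.345), on 1.40 ± 0.31 and 3.00 ± 0.15 CPM, miR-125b-2-3p at 0.45 (SE 0.15, adjusted p = 0.446) and miR-190b-5p at 0.60 (SE 0.21, adjusted p = 0.446).

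**Figure D1:**
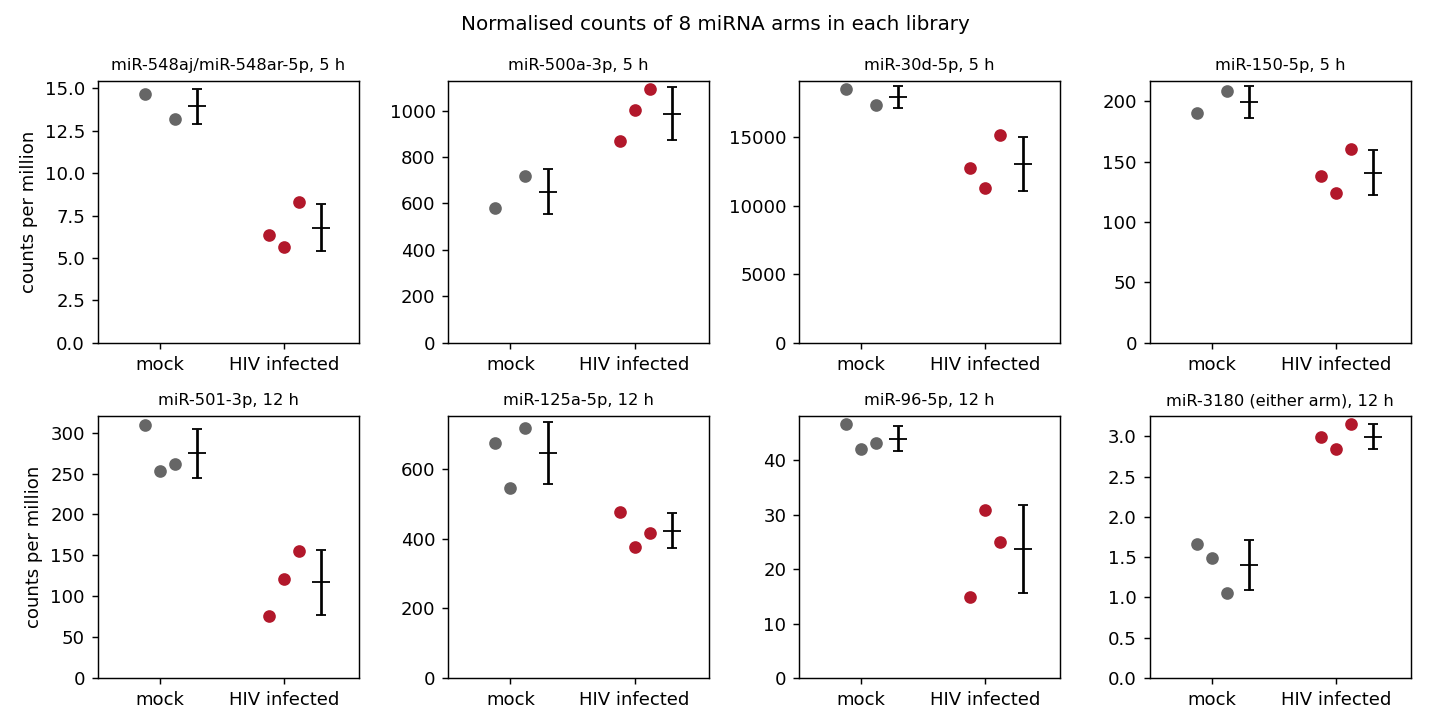
CPM of 8 miRNA arms in each library at 5 h (top) and 12 h (bottom), with grey points for mock and red points for HIV infected libraries. Bars give the mean and SD of each group (n = 2 mock at 5 h, n = 3 otherwise). The 2 groups do not overlap in any panel, but these arms were picked for their small p. Over all tested arms the groups did not overlap for 28.6% at 5 h and 15.2% at 12 h, where random grouping would give 20% and 10%. The first panel, miR-548aj/miR-548ar-5p at 5 h, is the 1 arm that passed adjusted p 0.05.

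At 12 h the miR-30 family had lower estimates in 5 of 5 arms, or 4 of 5 with RLE factors or without HIV infected library 2, mock library 1 or mock library 3, with miR-30a-5p at -0.81 (SE 0.33), or -0.25 without mock library 3, and miR-30e-5p at -0.26 (SE 0.13). None passed over all arms or when adjusted over the list alone. Higher estimates were found for 7 of 7 let-7 arms, with let-7c-5p at 0.22 (SE 0.13), but for only 4 of 7 with total counts, 5 of 7 without HIV infected library 2 and 6 of 7 without HIV infected library 1. In the miR-183 cluster miR-96-5p stood at -0.89 (SE 0.26), with 44.0 ± 2.33 CPM in mock and 23.7 ± 8.07 in infected libraries (SD, n = 3 each), and passed when adjusted over the list alone, but not without HIV infected library 1 or any 1 of the mock libraries. Of the interferon or NF-kB responsive arms, 6 of 9 had higher estimates, or 3 of 9 with total counts, and 1, miR-125a-5p, passed when adjusted over the list alone. None of that list did so without mock library 1 or 3 or HIV infected library 1 or 2, and 2 did without HIV infected library 3. Lymphocyte miRNAs were divided 6 to 6, with miR-342-3p at -0.41 (SE 0.13) and miR-146b-5p at 0.48 (SE 0.21), or 0.30 without HIV infected library 2, and 10 of 12 were lower with total counts and 9 of 12 without HIV infected library 3. Lower estimates were found for 3 of 3 miR-29 arms, with miR-29c-3p at -0.39 (SE 0.18), or -0.25 without HIV infected library 3, and for 6 of 10 arms of the miR-17~92 and paralog clusters, or 7 of 10 with total counts, but for only 3 of those 10 without HIV infected library 3 and 4 without mock library 2. The miR-15/16 family was divided 3 to 3, and 4 of 5 arms of the miR-232724 clusters had higher estimates. With total counts or without HIV infected library 2, 1 of 6 and 1 of 5 were higher, and without HIV infected library 3, 5 of 6 and 5 of 5 were. Of miR-221 and miR-222, 1 had a higher estimate, neither did with total counts, and both did without HIV infected library 3 or mock library 2.

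Of 9 arms of miRNAs reported to bind HIV RNA, 6 had lower estimates at 12 h. The estimate of miR-149-5p was -0.41 (SE 0.21), or -0.20 without HIV infected library 2 and -0.27 without mock library 3. Of 10 arms of miRNAs reported to act on host factors of HIV, 6 had lower estimates. The number was 9 with total counts, 8 without HIV infected library 2 and 3 without HIV infected library 3. The estimate of miR-20a-5p was -0.26 (SE 0.16), or -0.094 without mock library 2, -0.12 without HIV infected library 3 and -0.39 without HIV infected library 2. Of 5 p53-responsive arms 3 had higher estimates, with miR-192-5p at 0.27 (SE 0.12). That list's median was 0.16, its mean was -0.34 and camera's direction was up, and it held miR-143-3p at -1.98 (SE 0.91), or -0.59 without mock library 3. Mock library 3 stood apart in miR-143-3p, a miRNA of smooth muscle and fibroblasts, with 119, 256 and 1104 counts in the mock libraries against 99, 149 and 233 in infected libraries. It did so too in miR-199a/miR-199b-3p, another mesenchymal arm, with 169, 125 and 439 against 149, 140 and 216, and in miR-30a-5p, with 323, 200 and 571 against 262, 205 and 281. Mesenchymal or endothelial arms were divided 2 to 2, or 1 higher to 3 lower without HIV infected library 3. Epithelial arms were divided 3 to 3, or 4 higher to 2 lower without HIV infected library 1 or 2 or mock library 2 or 3, and with total counts 6 of 6 epithelial arms were lower. The myeloid or erythroid list had miR-486-5p alone, at 0.47 (SE 0.32), or 0.15 without HIV infected library 3 and 0.73 without HIV infected library 1, where it passed when adjusted over the list alone. The liver, muscle or neuron list had miR-9-5p alone, at -0.17 (SE 0.13), or -0.073 without mock library 3 and -0.11 without HIV infected library 1. The 14q32 and C19MC lists had no tested arm. None of 14 lists passed camera, with 1 at an unadjusted p under 0.05 and a smallest adjusted p of 0.251, and none passed fry. For the miR-30 family the unadjusted p was 0.0179 with camera and 0.261 with an estimated correlation, and without mock library 2 it passed camera (adjusted p = 0.0463), but not with an estimated correlation (adjusted p = 0.950).

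Whether the effect of infection differed between 5 and 12 h was tested over 236 arms. None passed (edgeR, 12 at an unadjusted p under 0.05), while 2 passed without HIV infected library 1 of 5 h and 1 without HIV infected library 2 of 12 h. The smallest p belonged to miR-96-5p, with a difference of -1.27 (SE 0.35, adjusted p = 0.255, or 0.0258 without HIV infected library 2 of 12 h), followed by miR-501-3p at -1.97 (SE 0.51) and miR-1271-5p at -2.62 (SE 0.74). The last was -1.71 without HIV infected library 3 of 5 h, and the 2 calls without HIV infected library 1 of 5 h were miR-501-3p and miR-1271-5p. In the mock cells alone, 12 h against 5 h gave 0 calls over the same arms, with 26 at an unadjusted p under 0.05, and here time and table cannot be separated. In that comparison the estimates were 0.76 (SE 0.26) for miR-96-5p, 1.51 (SE 0.39) for miR-501-3p and 2.01 (SE 0.56) for miR-1271-5p. The mock levels of these arms thus moved up between the tables, though not past the threshold. The mock change enters the differences above with a minus sign. An opposite sign is therefore likely for arms picked by those differences, and is no separate result.

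At 24 h the table held only part of each library, so the values show changes relative to the other arms in it. Under TMM scaling, 7 of 29 arms were relatively higher in infected cells and none was lower. They were miR-497-5p at 2.02 (SE 0.75, adjusted p = 0.032, with an estimate of 3.17 without mock library 1), ucuggcugaggaggaaguggagg at 1.80 (SE 0.61, adjusted p = 0.019), miR-3158-3p at 1.43 (SE 0.40, adjusted p = 0.0051), miR-1270-5p at 1.24 (SE 0.29, adjusted p = 0.0010), miR-4435-5p at 1.13 (SE 0.35, adjusted p = 0.010), miR-148a-3p at 1.12 (SE 0.30, adjusted p = 0.0049) and miR-129-5p at 1.10 (SE 0.37, adjusted p = 0.019). Each was higher in 3 of 3 infected libraries than in any mock library. Over the 29 arms the groups did not overlap, in either direction, for 34.5%, where random grouping would give 10%. None of the 7 was called without mock library 2 or without HIV infected library 2. Those called without mock library 3 were miR-1270-5p, miR-148a-3p and miR-3158-3p, those without HIV infected library 1 were miR-1270-5p and miR-497-5p, and without mock library 1 only miR-3158-3p was lost. Deposited counts were lower in the infected group for 27 of 29 arms, and the median arm had 3.10 times as many counts in the mock libraries. The abundant arm among the 7 was miR-148a-3p, encoded on chromosome 7 at 25949922 to 25949943 outside any same-strand host gene and known to target DNA methyltransferase transcripts. Its TMM-scaled level was 335140 ± 34371 CPM in mock and 726080 ± 235660 in infected libraries (SD, n = 3 each), which are not shares of the table. Its shares of the counts were 37.1%, 38.9% and 43.4% in mock and 62.4%, 62.0% and 51.7% in infected libraries. Its counts were 61393, 37398 and 44153 in mock and 34784, 36043 and 28038 in infected libraries. The others rested on few counts. miR-497-5p, of the miR-15/16 family, lies on chromosome 17 (7017978 to 7017999) and had 36, 4 and 4 counts in mock and 14, 21 and 17 in infected libraries. The sequence ucuggcugaggaggaaguggagg matched transcripts of BTBD10 and no miRNA precursor, with 38, 9 and 10 counts against 26, 18 and 15. miR-1270-5p, on chromosome 19 (20399320 to 20399342), had 157, 65 and 89 counts against 79, 88 and 58.

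The calls at 24 h depended on the scaling. With total counts the median of the shifts of single arms was -0.47, and 1 arm was higher and 2 were lower, against 7 and 0 with TMM. All 29 estimates moved down, and those of the 7 arms stayed positive, from 0.56 to 1.51. The arm called higher was miR-148a-3p, and those called lower were miR-17-5p at -0.97 (adjusted p = 0.0025) and miR-365a/miR-365b-3p at -1.16 (adjusted p = 0.033). Under TMM these were at -0.50 (SE 0.29) and -0.72 (SE 0.37) and did not pass, nor did miR-199a/miR-199b-3p at -0.50 (SE 0.29). Under TMM without HIV infected library 3, miR-365a/miR-365b-3p passed at -0.91 and miR-199a/miR-199b-3p at -0.58. The estimate of miR-365a/miR-365b-3p was -0.41 without HIV infected library 1, and those of miR-17-5p and miR-199a/miR-199b-3p were -0.79 and -0.77 without mock library 2. Few list members were in the table. Besides miR-497-5p and miR-17-5p, miR-29b-3p stood at -0.43 (SE 0.42), miR-125b-2-3p at -0.30 (SE 0.31), miR-24-3p at -0.03 (SE 0.30), miR-9-5p at 0.28 (SE 0.29) and miR-486-5p at 0.37 (SE 0.35), none past the threshold, and miR-9-5p and miR-486-5p turned negative with total counts. They did so too without mock library 1, at -0.074 and -0.044. With 1 library left out at a time, miR-29b-3p ran from -0.73 (without HIV infected library 3) to -0.19 (without HIV infected library 1), miR-125b-2-3p from -0.67 (without mock library 1) to -0.16 (without mock library 3) and miR-24-3p from -0.25 (without mock library 2) to 0.064 (without HIV infected library 1). No arm of the other 9 lists was tested, and no list test was run. No arm was called without mock library 2 or without HIV infected library 2. None was called with the zeros kept, with no count filter, with unmerged sequences or with the replicate number as a block. Without mock library 3 or without HIV infected library 1, 3 were called, and 17 without HIV infected library 3. Of the 7 arms, 2 were called when only arms listed under 1 sequence were tested. That test left out miR-148a-3p, miR-3158-3p and miR-497-5p, each under 2 end variants, and ucuggcugaggaggaaguggagg, under 3. With a mean count of at least 50, 1 was called, miR-1270-5p. Most of the 7 fell below that limit, and miR-148a-3p was tested there and did not pass.

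**Figure D2:**
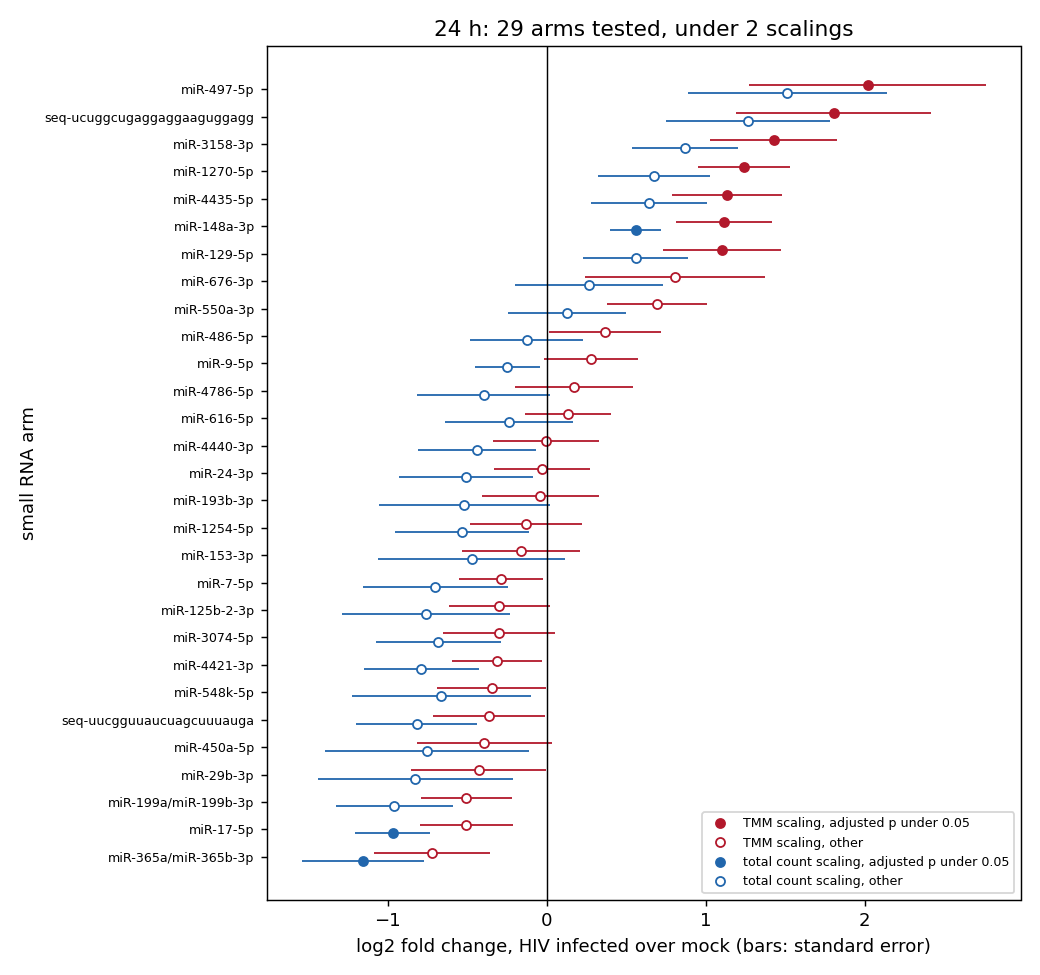
Log2 fold change of HIV infected over mock for the 29 arms tested at 24 h, with standard errors as bars (n = 3 libraries per group). Red is TMM and blue is total count scaling, and filled points passed adjusted p 0.05. All 29 estimates lie further left with total counts, and the 7 filled red points are reduced to 1 filled blue point on the right, with 2 on the left.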

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

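The tests of the depth and position of HIV infected library 3 and of the scaling at 24 h were chosen after the results were seen. No group held the 4 or more libraries that a test for outlying libraries needs.

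The estimates of miR-96-5p had opposite signs at 5 and 12 h, and neither passed over all arms (adjusted p = 0.279 and 0.431). Every infected library was above the mock libraries at 5 h, at 0.41 (SE 0.19), and below them at 12 h, at -0.89 (SE 0.26). The 5 h part was slight, with 29.8 CPM in 1 infected library against 29.5 in 1 mock library, and without HIV infected library 3 it was 0.17 (SE 0.20). The difference between the times, -1.27 (SE 0.35), did not pass the interaction test (adjusted p = 0.255, edgeR), though it did without HIV infected library 2 of 12 h (adjusted p = 0.0258), and the arm stood under 1 sequence in every library of both tables. In mock cells the estimate for 12 h against 5 h was 0.76 (SE 0.26, adjusted p = 0.220), and time and table cannot be separated.

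At 5 h the number of arms past the threshold rose from 1 to 29 without HIV infected library 3, which had 12236917 counts. The greater depth of library 3 does not by itself account for the low count with it. With library 3 thinned to the total of library 2, the median over 20 draws was 0 calls, with a range from 0 to 5 and 9 draws above 0. Thinning cannot test depth in the fit without library 3. There both infected libraries (3433474 and 2935841 counts) had fewer counts than either mock library (6013573 and 4976621), so depth and infection cannot be separated. Different end variants do not account for most of the arms, since 27 of the 29 stood under 1 sequence in all 4 libraries, the exceptions being miR-186-5p and the fragment ugucccuguucaggcgcca. A mock library under a wrong label cannot be told apart from a weaker response, because with 2 mock libraries the position of library 3 between mock and HIV, relative to the other infected library, had a median of 0.518 and ran from -0.0033 to 1.05. A smaller or later effect of infection in that library stays open and was not tested.

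At 24 h the 7 arms that were relatively higher in infected libraries had a higher mean GC content than the other 22, at 53.6% against 46.4%, and the log2 fold change followed GC across the 29 arms (Spearman's rho = 0.49, permutation p = 0.00779). After the linear trend on GC was taken out, 87% of the gap in log2 fold change was left (1.32, SE 0.17, against 1.51, SE 0.16). The 7 arms were picked by these same fold changes, so a gap is built in. The share left therefore cannot decide on GC, which stays open. With total counts 1 of the 7 was still called higher and 2 other arms were called lower, but that scaling moved all 29 arms down, so fewer higher calls follow from the shift alone, and all 7 estimates stayed positive, from 0.56 to 1.51. A loss of most small RNAs of the table in infected cells and a gain of these 7 arms would give the same relative values, and both stay open. The real split of the 6 libraries gave 7 calls, and 1 of the 10 splits, the real one, gave as many, with 3 as the highest of the others, but the splits are too few for a share under 0.05.

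Without HIV infected library 3 the 24 h calls rose from 7 to 17, with 11 higher and 6 lower. Between mock and HIV, library 3 lay at 0.245 of the distance of the other infected library (median of 12 choices of libraries, from 0.147 to 0.420). A weaker effect in this library may account for the lower count with it. A wrong label or a mixture with mock RNA would also place it there, and these stay open.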

How the results depend on the processing

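The alternatives that used the summed rows, kept zeros, unmerged sequences, arms listed under 1 sequence and the thinned library were chosen after the data were seen. At 5 h, where 1 arm was called, the count was 0 with DESeq2, RLE factors, total counts, a mean count of at least 50, summed rows or unmerged sequences. With library 3 thinned it was from 0 to 5 over 20 draws, with a median of 0. It was 7 with no count filter, 4 with zeros kept and 3 with arms listed under 1 sequence (miR-548aj/miR-548ar-5p, miR-30d-5p and miR-616-5p), and from 0 to 29 when each library was left out. Without mock library 2 it was 3, without HIV infected library 1 it was 5 and without HIV infected library 2 it was 0. With robust=FALSE 1 arm was called, ugucccuguucaggcgcca in place of miR-548aj/miR-548ar-5p. When a mock library is left out, the lone one is assumed to vary like the infected libraries. The miR-548aj/miR-548ar-5p estimate stayed negative in each fit that held the arm, with an adjusted p from 0.0023 to 0.403. At 12 h, where none was called, the count was 1 with DESeq2, 2 with no count filter, 2 with zeros kept, 1 with unmerged sequences, and from 0 to 1 when each library was left out. It stayed 0 with RLE factors, total counts, a mean count of at least 50, robust=FALSE, summed rows and arms listed under 1 sequence. At 24 h the 7 arms were all called again with DESeq2, RLE factors and summed rows, and 6 of them with robust=FALSE. The 24 h count was 3 with total counts, 1 with a mean count of at least 50, 0 with no count filter, 0 with zeros kept, 0 with unmerged sequences and 2 with arms listed under 1 sequence, and from 0 to 17 when each library was left out. More arms are adjusted for with no filter, zeros kept or unmerged sequences, and fewer are tested with the stricter limits. The 4 arms called at 5 h with zeros kept were miR-1180-3p, miR-6511a-3p, acccugcucgcugcacca and gaauaccaggugcuguaggcuuc. All 4 were at 0 in every library of one group and above 0 in every library of the other. They were also among the 7 called with no count filter, a fit that kept zeros too. The main test, limited to arms above 0 in every library, left them out. Otherwise the cause was not tested. The interaction count, 0, was 0 with RLE factors and from 0 to 2 when each library was left out, with 2 without HIV infected library 1 at 5 h and 1 without HIV infected library 2 at 12 h. No list passed camera with RLE factors or an estimated correlation, and with 1 library left out only the miR-30 family did, without HIV infected library 3 at 5 h and without mock library 2 at 12 h. Both were lost with an estimated correlation (adjusted p = 0.915 and 0.950).

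Replicate numbers did not clearly pair the libraries, and pairing is not excluded. Same-numbered libraries had deviation correlations of -0.211 and 0.073 at 5 h, 0.074, 0.246 and 0.254 at 12 h, and -0.175, -0.049 and -0.172 at 24 h. At 12 h every infected library correlated best with the mock library of its own number. Mock library 1 was the exception, at 0.076 with HIV infected library 2 against 0.074 with library 1. At 5 h the 2 mock libraries mirror each other, so they say little about pairing. A replicate block gave 20 calls at 5 h (8 higher, 12 lower) and 0 at 12 h, 24 h and for the interaction. Only the miR-30 family at 5 h passed camera (adjusted p = 0.0384, or 0.951 with an estimated correlation). At 5 h HIV infected library 3 has no mock partner, so the block fit largely restates the fit without it.

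Some estimates, none past the threshold, changed sign, and the cause was not tested. With a mean count of at least 50, miR-221-3p at 5 h went from 0.03 to -0.00287, and miR-24-3p at 24 h from -0.03 to 0.081. With library 3 thinned, miR-221-3p at 5 h was -0.0027. With total counts, miR-222-3p at 12 h was -0.014, and at 24 h miR-9-5p was -0.25 and miR-486-5p -0.13. When each library was left out at 5 h, miR-29b-3p ran from -0.026 to 0.31, miR-222-3p from -0.37 to 0.0061 and miR-221-3p from -0.060 to 0.069. At 12 h, miR-15a-5p ran from -0.17 to 0.075, miR-27a-3p from -0.18 to 0.0092, miR-24-3p from -0.10 to 0.43, miR-183-5p from -0.17 to 0.034, miR-221-3p from -0.10 to 0.075 and miR-200b-3p from -0.25 to 0.00673. At 24 h, miR-24-3p ran from -0.25 to 0.064, miR-9-5p from -0.074 to 0.47 and miR-486-5p from -0.044 to 0.53. Of the alternative values of single arms, 20 changed sign, 67 lost and 19 gained the threshold, and 1094 did neither. The planned fit of only the 2 groups compared was not run, because the tables hold no other group, and the alternatives for normalized values or authors' comparisons do not apply to counts. Counts of 10 or fewer, as for miR-497-5p in 2 mock libraries at 24 h, limit what can be seen.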

Other observations

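Families and genomic neighbours outside the fixed lists were grouped after the data were seen, as were the tests of the tRNA fragment and of the on or off rows. At 5 h, 6 of 6 tested arms of the miR-548 family had lower estimates in infected cells, with a median of -0.38, and 7 of 7 arms from the CLCN5 intron cluster on chromosome X had higher ones, with a median of 0.48, and both counts were the same with RLE factors and total counts. The miR-548 median was -0.21 without mock library 1 and -0.71 without HIV infected library 3, with 6 of 6 lower each time. The X cluster median was 0.31 without HIV infected library 3, and 6 of 7 were higher without mock library 1 or without HIV infected library 1 or 2. That cluster holds miR-188, miR-362, miR-500a, miR-501, miR-532 and miR-660. Of 14 families and clusters with at least 3 tested arms, these 2 passed camera with the preset correlation (adjusted p = 0.00077 and 0.0060), and neither passed with an estimated one (adjusted p = 0.797 and 0.564). Without mock library 1 neither passed with the preset correlation (adjusted p = 0.0813 and 0.158), and without HIV infected library 3 the miR-30 family (lower) and the miR-17~92 cluster (higher) passed too, but not with an estimated correlation (adjusted p = 0.529 and 0.946). At 12 h, none of 15 passed, but miR-548 and miR-30 did without mock library 2 (adjusted p = 0.032 each), and the miR-17~92 cluster (lower) did without HIV infected library 2 (adjusted p = 0.036). With an estimated correlation none of these 3 passed (adjusted p = 0.920 for the first 2 and 0.778 for the cluster). The miR-548 family had 5 of 6 arms with lower estimates (median -0.44, adjusted p = 0.180), with a median of -0.20 without HIV infected library 2, and 5 of 7 arms of the X cluster had lower ones (median -0.09, adjusted p = 0.581). Without mock library 2 or HIV infected library 3, 5 of 7 of the X cluster were higher.

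A hypothesis is that arms encoded within 10 kb of each other change together. At 5 h the mean absolute difference in log2 fold change over 62 such pairs was 0.223, against 0.317 for random pairs (permutation p = 0.0145), and p was 0.0851 without HIV infected library 2. At 12 h it was 0.337 over 68 pairs against 0.377 (permutation p = 0.341), so the test was met at 1 time and not at the other, and co-regulation may hold at 5 h only or not at all.

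The 3' end of tRNA-Lys, whose last bases gucccuguucgggcgcca pair with the HIV-1 primer binding site, was listed as a small RNA. A hypothesis is that it is at least 1.5 times more abundant in infected cells at 12 h. It stood at 817 ± 113 CPM in mock and 786 ± 289 in infected libraries (SD, n = 3 each), with a log2 fold change of -0.056 (SE 0.27) and an upper bound of 0.48 at 2 SE, below the 0.585 of a 1.5-fold change. HIV infected library 3 had the lowest level, and without it the estimate was 0.27 (SE 0.16, upper bound 0.596). The upper bound was 0.678 without mock library 1 and 0.738 without mock library 2, so the hypothesis stays open. At 5 h the estimate was 1.25 (SE 0.61, adjusted p = 0.559, edgeR), or 0.77 without mock library 1 and 1.95 without mock library 2, but 1 mock library listed only the shorter end variant. A fragment with a similar end, ugucccuguucaggcgcca, went the other way at 5 h. It stood at -2.33 (adjusted p = 0.279, edgeR), or at -1.96 without HIV infected library 3 (adjusted p = 0.047, edgeR).

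In the deposited rows, 60 sequences were at 0 in every library of one group and above 0 in every library of the other, 48 of them at 5 h, 11 at 12 h and 1 at 24 h. Of these, 30, or 50%, belonged to an arm listed in the group at 0 under another sequence, or to a precursor whose other arm was listed there. That is exactly at the limit set for the hypothesis that end variants and arm choice, rather than loss of the miRNA, are behind them. For the other 30 no such listing was found, and those rows stay open. At 5 h, 44 of the 48 were off in infected libraries, among them miR-1180-3p. Of the 3 infected libraries, 2 had fewer counts than either mock library. HIV infected library 3 had more than either, at 12236917, and by definition these 44 rows were at 0 there too.

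At 12 h the real split of the 6 libraries gave 0 calls, so 10 of 10 splits gave as many whatever their counts, and this tests nothing. The highest of the others was 0. The splits are too few for a share under 0.05. Across arms, the fold changes at 5 and 12 h were nearly unrelated (Pearson's r = 0.07, Spearman's rho = 0.18, 233 arms, 135 of the same sign). Those at 12 and 24 h had r = 0.48 and rho = 0.63 over 29 arms, 23 of the same sign. Arms are not independent replicates, and no test was run on these correlations.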
